A study of Homo sapiens with 6 samples.

How the data were processed

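RNA-seq was made from LP-1 cells carrying a guide against AURKA (3 libraries) or a guide without a target (3 libraries), sequenced with the BGISEQ-500 protocol per the labels. The labels do not say whether the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Per the submitters' processing notes, BWA, Bowtie2, RSEM and the genome build hg19 were used; their versions, roles and settings, the RNA selection and the strandedness are not given in the sources used here. The authors deposited a gene table and a transcript table of expected counts, which RSEM estimates by dividing reads among transcripts and which need not be whole (44.8% of the gene values were not). Per the file headers, the gene table also holds FPKM values, the authors' counts per kilobase and per library size. The authors' deposited comparison tables give log2 fold changes and adjusted p-values (q-values), with DESeq2 named in the file headers. The gene comparison covers the AURKA guide, and the transcript comparison the AURKA guide and an NSD2 guide, whose libraries were not analysed here.

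Total expected counts ran from 17724174 to 18523594 per library. Normalised counts are given as CPM, the usual scaling of counts to library size, and a gene at 1 CPM has about 18 reads here. Reads without molecular identifiers are not independent molecules, and every test used the spread between libraries rather than counting error alone. Replicates differed by more than counting noise, so none is a copy of another: the chi-square per gene over genes with at least 20 reads was between 2.24 and 10.5 in pairs of 1 group. The tables held 17579 genes and 84276 transcripts. Gene symbols came from the gene table, and 76 that a spreadsheet had turned into dates or that were plain numbers were replaced by name through the gene ID where possible; 17316 IDs matched a RefSeq gene. Transcript GC content and length came from the longest coding transcript per gene in GENCODE release 29 and were found for 17002 genes. Because that annotation and the RefSeq table belong to another build than the authors' hg19, no coordinates are given.

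Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr (13138 genes), libraries scaled by TMM, and the groups compared by the quasi-likelihood F test with Benjamini-Hochberg adjustment at 0.05. Fold changes are log2 of AURKA guide over control, and their standard errors come from the F statistic. CPM values use the TMM-scaled library size. Transcripts were tested in the same way. On data simulated from these libraries with 200 changed genes among 13023 to 13048 (5 draws), the test recovered 63.2% of genes changed 1.25-fold, 86.4% of those changed 1.5-fold, 96% of 2-fold and 100% of 4-fold changes, and 6.9% of its calls were false. The simulation drew each gene on its own, without the trends with GC content that the real libraries show. These shares may therefore not hold for the real libraries. The 25 gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 and adjustment over the 21 lists with at least 2 tested members. Members were also adjusted over their own list alone. That step was not among the fixed tests and is not corrected over the lists, so its counts are more lenient. Of the 6 lists that camera called, 3 were called with an estimated correlation (replication, histones, cholesterol synthesis), and fry, which asks whether a list's genes move on balance one way and does not compare them with other genes, also called 6.

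The named genes are AURKA and NSD2; the 10 largest rises and 10 largest falls among changed genes with at least 5 CPM on average whose groups do not overlap; in each list the 3 members with the smallest p and at least 5 CPM; and the 5 largest rises and falls in the authors' deposited gene table. Other list members are named for their call or their values, which were seen first, and some genes that the rule names are not reported here. Several genes that share reads with close copies or overlapping genes are marked as uncertain, but not every such gene is.

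Alternatives were the replicate number as a block, each library left out, no filter or a mean of at least 10 CPM, DESeq2 size factors or library size alone, the DESeq2 1.42.0 Wald test, limma-trend on log2(FPKM + 1) for genes with at least 0.5 FPKM in 3 libraries, and a minimum absolute log2 fold change of 1. The FPKM pseudocount was not varied because those values were not the main measure. Chosen after seeing the data were 7 further gene lists, DESeq2 on transcripts, and corrections for GC content, alone or with length, by a natural spline (5 degrees of freedom) of each library's deviation from the mean library used as an offset; these were made also with each library left out. An unnamed column of the deposited gene comparison was not used. Figures were drawn with matplotlib 3.10.9.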

Results

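Gene expression was measured by RNA-seq in LP-1, a human multiple myeloma cell line carrying the t(4;14) translocation, which places NSD2 and FGFR3 under immunoglobulin control. Cells had received a virus with a guide against AURKA, the gene of the mitotic kinase Aurora A, or a guide with no target. Each group had 3 libraries, referred to here as the AURKA-guide and control libraries. The gene table held 17579 genes, and the total expected count per library lay between 17724174 and 18523594. Control replicates 1 to 3 are written C1 to C3 and AURKA-guide replicates 1 to 3 A1 to A3. Where a call was lost in a fit without 1 library, that library is named with the adjusted p without it. Such a fit has fewer libraries and less power, so a lost call does not by itself show that a gene rests on that library. The series title links Aurora A to the histone methyltransferase NSD2 and to drug resistance, and the 1 comparison the design gives is AURKA guide over control.

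AURKA (gene ID 6790) fell by 0.74 on the log2 scale in the AURKA-guide libraries (SE 0.0488, edgeR quasi-likelihood adjusted p = 1.55e-06), to 0.599 of the control level. Its normalised read count was 192.02 ± 2.85 CPM (counts scaled to library size) in control and 115 ± 3.86 in AURKA-guide libraries (SD, n = 3 each). The expected counts were 3498, 3364 and 3627 in control replicates 1, 2 and 3, and 2062, 2191 and 2079 in AURKA-guide replicates 1, 2 and 3. A guide-directed break need not remove a transcript, so the RNA that is left does not measure the protein. NSD2 (gene ID 7468) was at 376 ± 7.62 CPM in control and 369.6 ± 7.16 CPM in AURKA-guide libraries (SD, n = 3 each), a log2 difference of -0.02 (SE 0.044, adjusted p = 0.822) that lay within the spread between replicates.

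Beyond AURKA itself, the AURKA-guide cells had higher RNA of IGFBP3, a binding protein of insulin-like growth factors, and lower RNA of HES7 and TLE2, transcriptional repressors linked to Notch signalling, of the cell cycle inhibitor CDKN1A (p21) and of the interleukin 6 receptor IL6R. IGFBP3 rose 1.896-fold, from 131.4 ± 1.15 to 249.1 ± 1.23 CPM (SD, n = 3 each; adjusted p = 5.36e-08). OLFML2A, an extracellular matrix protein, rose by 0.94 on the log2 scale (SE 0.0723), the lens crystallin CRYBB1 by 1.34 (SE 0.133) and the kinase SGK1 by 0.73 (SE 0.0975). HES7 fell by 1.76 (SE 0.131), TLE2 fell by 1.23 (SE 0.114), CDKN1A fell by 0.86 (SE 0.0948) and IL6R fell by 0.74 (SE 0.0719). The hair keratins KRT81 and KRT86 rose by 1.30 (SE 0.0899) and 1.13 (SE 0.0801), but they are close copies whose reads can be divided wrongly. The largest rises with a mean of at least 5 CPM also held HIST1H1C, HIST1H2BJ and HIST1H3G (below with the histones) and PLA2G4B at 1.18 (SE 0.255), which overlaps a readthrough gene and whose call was lost without 3 of the libraries (A1 0.0748, A2 0.0781, A3 0.143). The size of the PLA2G4B rise also depended on C2, with 22.1 expected counts beside 73 in C1 and 77.3 in C3, and was 0.82 without C2. Among the largest falls were also CRIP1 (-0.72, SE 0.11), a LIM-domain protein, MISP3 (-0.80, SE 0.138), the endocytic receptor LRP1 (-0.71, SE 0.125) and ITM2A (-0.70, SE 0.125). Calls were lost for MISP3 (A2 0.0602), LRP1 (C1 0.0509, A2 0.0597, A3 0.0507) and ITM2A (C1 0.0618, A2 0.0626).

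**Figure D1:**
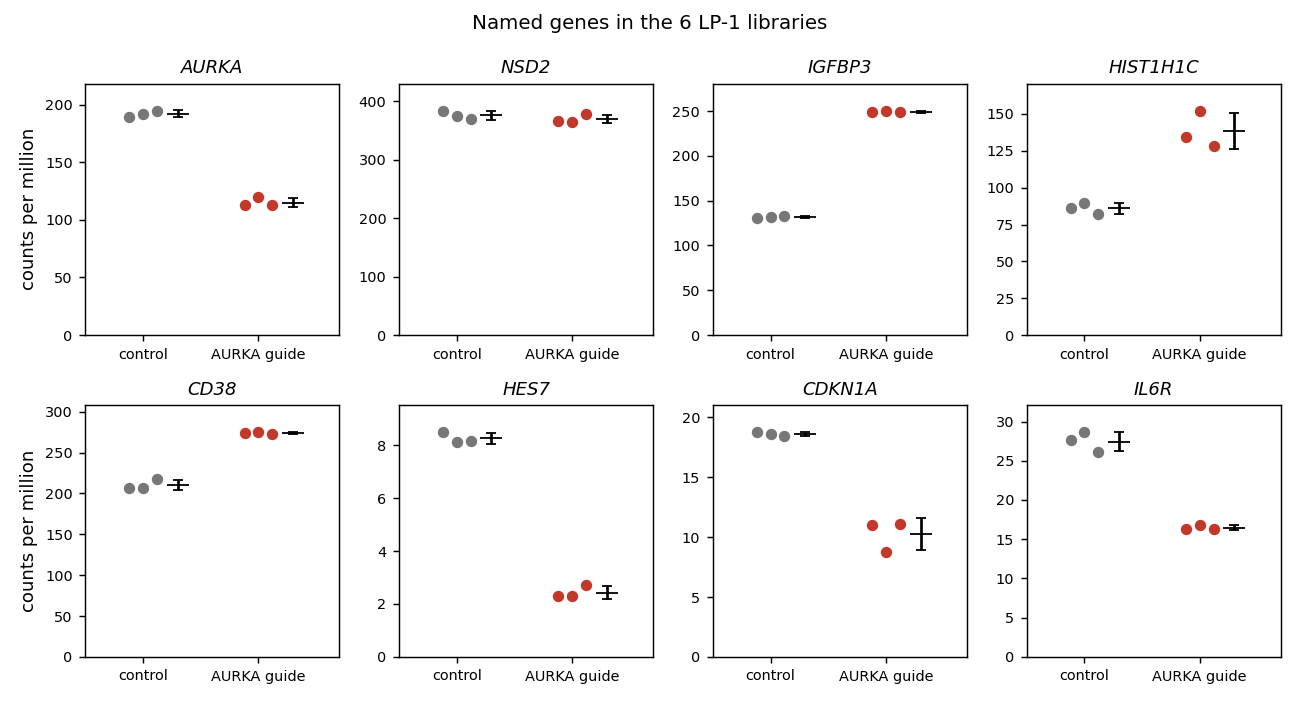
Normalised read counts (CPM, axis from 0) of 8 named genes in the 3 control (grey) and 3 AURKA-guide (red) libraries; bars give the mean ± SD. AURKA, HES7, CDKN1A and IL6R lie lower and IGFBP3, HIST1H1C and CD38 higher in all 3 AURKA-guide libraries, while the NSD2 values overlap.

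Of 13138 genes tested, 267 passed an adjusted p of 0.05 (edgeR), 126 higher and 141 lower in AURKA-guide libraries, and 36 of them, 17 higher and 19 lower, differed by at least 1 on the log2 scale. The count differed between the fits that left out single libraries, which have less power, and after a correction for transcript GC content. It was 111 without control replicate 1, 2034 without control replicate 3, and 154, 101 and 98 without AURKA-guide replicates 1, 2 and 3, with 71 genes past the threshold in each of the 6 fits that left a library out, and it was 866 after a correction for GC content.

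**Figure D2:**
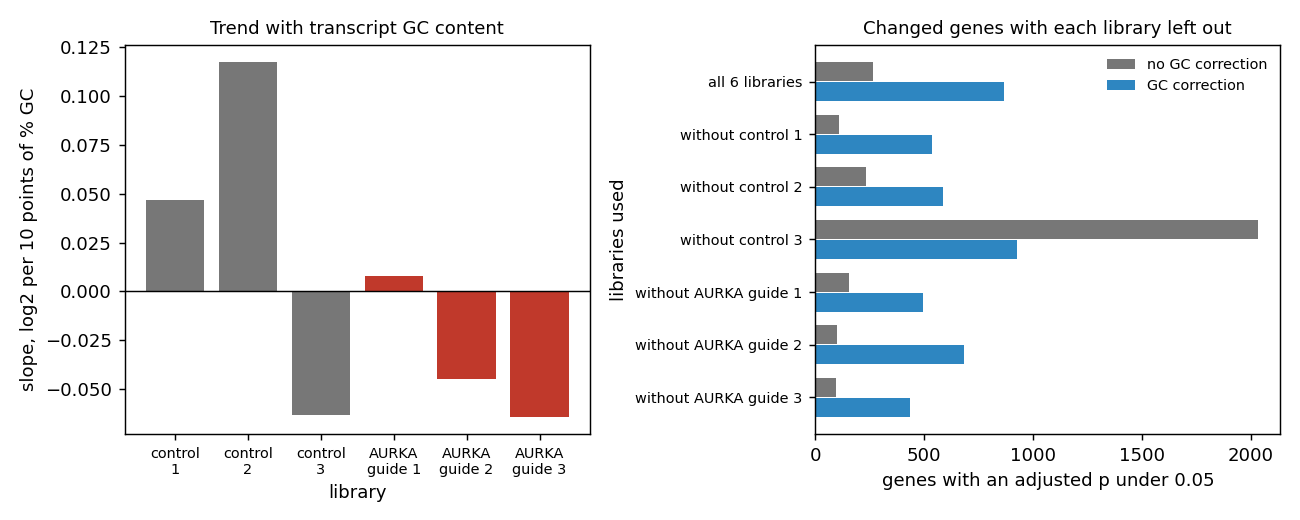
Left, slope of each library's log2 deviation from the mean library on transcript GC content (log2 per 10 points of GC percent). Right, number of genes with an adjusted p under 0.05 in all 6 libraries and with each left out, without (grey) and with (blue) GC correction; the count of 2034 without control replicate 3 is 927 with the correction.

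Some genes of mitosis were higher in AURKA-guide libraries. Of 30 genes of G2/M and mitosis, 6 rose and none fell, and 23 rose when adjusted over the list alone; the median log2 fold change was 0.19. The checkpoint kinase BUB1 rose by 0.29 (SE 0.0432, adjusted p = 0.0020), topoisomerase TOP2A by 0.31 (SE 0.0559, adjusted p = 0.0081) and the spindle protein ASPM by 0.28 (SE 0.0516, adjusted p = 0.0086), followed by CENPF, CDK1 and HMMR. BUB1 kept its call without each library in turn, while the other 5 lost it: TOP2A (A2 0.0626, A3 0.0862), ASPM (C1 0.0702, A3 0.102), CENPF (C1 0.0942, A1 0.0687, A3 0.126), CDK1 (C1 0.213, C2 0.0526, A1 0.0547, A2 0.226, A3 0.178) and HMMR (C1 0.276, C2 0.0785, A1 0.0923, A2 0.189, A3 0.286). The list was called by camera (adjusted p = 1.81e-16) but not when the correlation between its genes was estimated (adjusted p = 0.112 with an estimated correlation). Its transcripts had a median GC content of 42.2%, against 48.5% for all tested genes, and after the GC correction the median was 0.13. Among 14 tested partners and relatives of Aurora A, only AURKA changed over all genes. Adjusted over the list alone, 3 were higher and 1 lower. The centrosome protein CEP192 was at 0.28 (SE 0.0685, adjusted p = 0.0540) and the microtubule polymerase CKAP5 at 0.15 (SE 0.0459, adjusted p = 0.1200), while the mitotic kinases PLK1 and AURKB were at 0.0078 (SE 0.0503) and -0.0031 (SE 0.0562). CEP192 and CKAP5 passed without C3 (adjusted p = 0.0139 and 0.00959) and after GC correction (0.0142 and 0.0125). That list was not called (camera adjusted p = 0.698).

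None of 28 genes of DNA replication passed over all genes, 7 were higher when adjusted over the list alone, and the list as a whole was shifted up (median 0.07, camera adjusted p = 1.04e-05, adjusted p = 0.0409 with an estimated correlation). The helicase subunits MCM6 and MCM4 were at 0.17 (SE 0.0481, adjusted p = 0.0904) and 0.15 (SE 0.0441, adjusted p = 0.101) and the ribonucleotide reductase subunit RRM1 at 0.17 (SE 0.0494, adjusted p = 0.1100). These 3 passed without C3 (0.00522, 0.0131 and 0.00429) and after GC correction (0.00696, 0.00345 and 0.0189). Of 13 tested replication-dependent histone genes 7 rose and none fell, with 9 higher when adjusted over the list alone and a median of 0.43. The linker histone gene HIST1H1C rose 1.613-fold (log2 SE 0.0646, adjusted p = 3.98e-05), HIST1H2BK 1.497-fold (log2 SE 0.0557, adjusted p = 4.7e-05) and HIST2H2BE by 0.42 on the log2 scale (SE 0.0589, adjusted p = 0.0015). These genes are known to give polyadenylated transcripts beside the usual ones. HIST1H2BJ and HIST1H3G, outside the list, rose by 0.69 (SE 0.115) and 0.66 (SE 0.117), the latter not past the threshold without 1 library (C1 0.0623). HIST2H2AA3, 1 of the 7, is a copy of HIST2H2AA4 and uncertain. The histone list was called with camera (adjusted p = 7.6e-11, and adjusted p = 0.0409 with an estimated correlation); of its 7 risen members, 4 kept their calls without each library in turn. Calls were lost for HIST1H2BD (A2 0.0751, A3 0.0564), HIST2H2AA3 (C1 0.056, A2 0.0621) and HIST1H4H, at 2.41 CPM (C1 0.164, A1 0.102, A2 0.121, A3 0.0988).

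**Figure D3:**
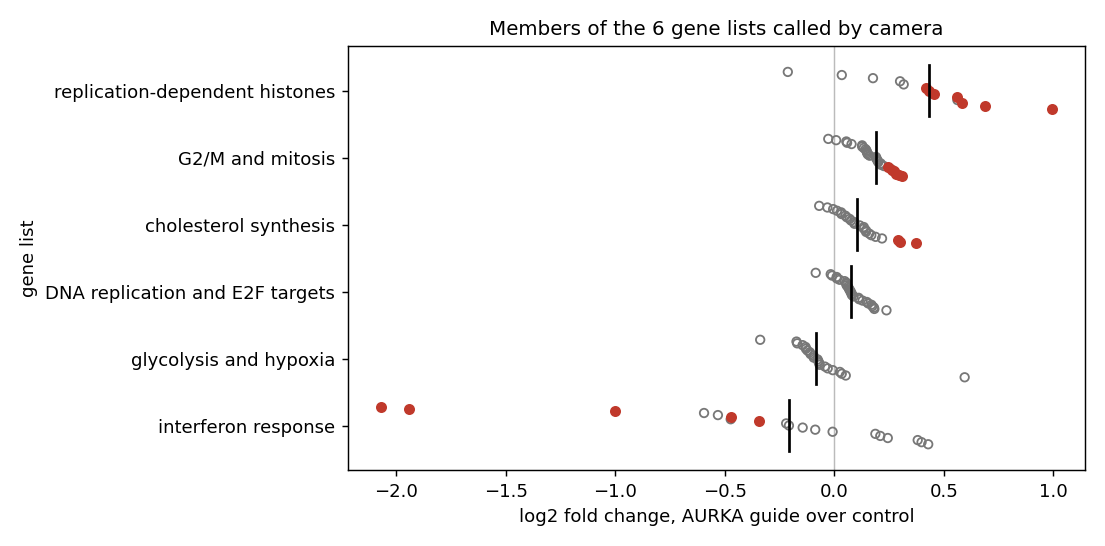
Log2 fold change (AURKA guide over control) of each tested member of the 6 gene lists that camera called; filled red points have an adjusted p under 0.05, open points do not, and the vertical bar is the list median. Medians run from 0.43 for the replication-dependent histones to -0.21 for the interferon response, whose members lie on both sides of 0.

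Enzymes of cholesterol synthesis were shifted up. Of 24 tested, 3 rose and none fell, and 6 rose when adjusted over the list alone (median 0.10, camera adjusted p = 3.24e-06, adjusted p = 0.0409 with an estimated correlation). The sterol oxidase MSMO1 rose by 0.37 (SE 0.0652, adjusted p = 0.0068), HMGCS1, which makes HMG-CoA, by 0.30 (SE 0.0572, adjusted p = 0.0111) and the isomerase IDI1 by 0.29 (SE 0.058, adjusted p = 0.0155). All 3 calls were lost without some of the libraries: MSMO1 (A2 0.0683, A3 0.0539), HMGCS1 (C1 0.105, A2 0.0948, A3 0.097) and IDI1 (C1 0.136, A1 0.0501, A2 0.14, A3 0.0784). No gene of glycolysis and hypoxia passed among 22, over all genes or adjusted over the list alone, and the list was shifted down (median -0.09, camera adjusted p = 0.00529, adjusted p = 0.140 with an estimated correlation). VEGFA was at -0.17 (SE 0.0528, adjusted p = 0.131), MXI1 at -0.15 (SE 0.053) and PFKFB4 at -0.34 (SE 0.129). VEGFA passed without C3 (0.0150), and VEGFA and MXI1 after GC correction (0.0120 and 0.00786). The estimated-correlation calls of the replication, histone and cholesterol lists were each lost when any 1 library was left out, with the same adjusted p for the 3 lists (C1 0.117, C2 0.0569, C3 0.130, A1 0.142, A2 0.114, A3 0.0803).

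Antiviral genes of the interferon response were lower in part. Of 19 tested, 5 fell and none rose, and adjusted over the list alone 6 were lower and 1 higher (median -0.21, camera adjusted p = 0.00191, adjusted p = 0.0995 with an estimated correlation). The RNA sensor OAS2 fell by 2.07 (SE 0.185, adjusted p = 2.83e-05), OAS1 fell to 0.4996 of the control level (log2 SE 0.206, adjusted p = 0.0182) and IFI6 fell by 0.47 (SE 0.101, adjusted p = 0.0235), as did IFITM1 at 0.494 CPM. HERC5 was at 0.40 (SE 0.116, adjusted p = 0.108) and CXCL10 at 0.21 (SE 0.0845, adjusted p = 0.240), in the other direction, and IRF7 at -0.60 (SE 0.149, adjusted p = 0.0567; 0.00339 without C3 and 0.0198 after GC correction). Of the 5, only OAS2 kept its call without each library in turn. Calls were lost for OAS1 (C1 0.0683, A2 0.123, A3 0.135), IFI6 (C1 0.112, C2 0.0537, A2 0.117, A3 0.153) and IFITM1 (C1 0.0919, A1 0.0547, A2 0.0751, A3 0.104). Many of these genes were at a few CPM, and among genes with a mean of at least 10 CPM the list was not called (adjusted p = 0.160, with a range over all alternatives from 2.31e-05 to 0.160).

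Of 23 tested p53 targets, CDKN1A fell and the death receptor FAS rose by 0.31 (SE 0.0552, adjusted p = 0.0074; C1 0.0683, A3 0.0775), the same 2 genes as when adjusted over the list alone. SESN1 was at -0.29 (SE 0.106, adjusted p = 0.199; 0.0386 after GC correction) and MDM2, a direct p53 target, at 0.09 (SE 0.0767, adjusted p = 0.585). The list was not called (camera adjusted p = 0.996). Of 15 immediate early genes EGR1 rose 3.846-fold, at a mean of 2.23 CPM (log2 SE 0.229, adjusted p = 3.67e-04), and KLF2 fell by 0.30 (-0.18 after GC correction; SE 0.0685, adjusted p = 0.0378; C1 0.0919, C2 0.0824, A1 0.0949, A2 0.14, A3 0.269). Adjusted over the list alone, 2 were higher and 2 lower. KLF6 and JUNB were at 0.17 (SE 0.0529) and 0.21 (SE 0.0837), and the list was not called (camera adjusted p = 0.137). It was called without C2 (0.0021) and after GC correction (0.00256), but in neither case with an estimated correlation (adjusted p = 0.212 and adjusted p = 0.156 with an estimated correlation). KLF6 passed without C3 (0.0147) and after GC correction (0.0120), and JUNB without C2 (0.0273) and after GC correction (0.32, adjusted p = 9.45e-05).

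Plasma cell genes moved both ways. Of 19 tested, CD38, the ectoenzyme targeted by myeloma antibodies, rose 1.301-fold, from 210.3 ± 6.004 to 273.6 ± 1.14 CPM (SD, n = 3 each; adjusted p = 4.16e-04), and DERL3, of endoplasmic reticulum protein disposal, rose by 0.41 (SE 0.0711, adjusted p = 0.0067), while the reticulum chaperone FKBP11 fell by 0.27 (SE 0.0543, adjusted p = 0.0173). The counts were the same when adjusted over the list alone, 2 higher and 1 lower. Calls were lost for DERL3 (A2 0.0545) and FKBP11 (C1 0.109, A1 0.0599, A2 0.0978, A3 0.162), and the list was not called (camera adjusted p = 0.698). Of 17 genes of adhesion and homing the filament protein VIM fell by 0.26 (SE 0.0414, adjusted p = 0.0037), the chemokine receptor CXCR4 was at 0.21 (SE 0.0516, adjusted p = 0.0519) and ICAM1 at 0.13 (SE 0.0506, adjusted p = 0.241), with 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.823). Of 7 genes high in t(4;14) myeloma the receptor kinase FGFR3 fell by 0.24 (-0.14 after GC correction; SE 0.0565, adjusted p = 0.0424), a call lost in 5 of the 6 fits without a library (C1 0.209, C2 0.0808, A1 0.0633, A2 0.232, A3 0.269). The cyclin gene CCND2 was at 0.13 (SE 0.0439, adjusted p = 0.149), and CCND2 and CXCR4 passed without C3 (0.0151 and 0.00333) and after GC correction (0.0145 and 0.0041), as did ICAM1 after GC correction (0.00197). In the t(4;14) list, adjusted over the list alone 1 was higher and 1 lower (camera adjusted p = 0.698).

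In 7 further lists no member passed, over all genes or adjusted over the list alone. Among 15 histone H3 lysine 36 methyltransferases, demethylases and related genes, SMYD2 was at 0.23 (SE 0.0703, adjusted p = 0.130), ASH1L at 0.10 (SE 0.0543) and EZH2 at 0.09 (SE 0.0542), with a camera adjusted p = 0.782. Among 12 members of the BCL2 family of apoptosis regulators, BAK1 was at -0.17 (SE 0.0512, adjusted p = 0.123), BCL2 at 0.12 (SE 0.0551) and BAD at -0.17 (SE 0.0925), with a camera adjusted p = 0.823. Among 23 genes of the unfolded protein and integrated stress response, CEBPB was at -0.21 (SE 0.0816), HSP90B1 at 0.11 (SE 0.0488) and CRELD2 at -0.16 (SE 0.0738), with a camera adjusted p = 0.782. The 17 proteasome subunits, the complex that bortezomib blocks, had a median of -0.0018 and a camera adjusted p = 0.823, with PSMB3 at -0.10 (SE 0.0576), PSMB1 at 0.10 (SE 0.0604) and PSMB7 at 0.09 (SE 0.0565). Among 14 targets of NRF2 and drug efflux pumps, the pump gene ABCC1 was at 0.13 (SE 0.0516, adjusted p = 0.233), TXNRD1 at 0.11 (SE 0.0506) and GCLC at 0.13 (SE 0.0691), with a camera adjusted p = 0.698. Among 23 genes of MYC and ribosome biogenesis, NPM1 was at 0.15 (SE 0.0549), SRM at -0.18 (SE 0.0704) and NOP58 at 0.13 (SE 0.0614), with a camera adjusted p = 0.782. Among 16 NF-kB targets, BIRC3 was at 0.24 (SE 0.0705, adjusted p = 0.119), TNFAIP3 at 0.13 (SE 0.0446) and ICAM1 at 0.13 (SE 0.0506), with a camera adjusted p = 0.782. Calls in these lists depended on C3 and on GC content. Passing without C3 were BAK1 (0.00768), BCL2 (0.0393), BAD (0.0115), CEBPB (0.0110), HSP90B1 (0.0146), CRELD2 (0.0251), PSMB3 (0.0413), GCLC (0.0358), NPM1 (0.0024), SRM (0.00306), NOP58 (0.00779) and BIRC3 (0.000729). Passing after GC correction were ABCC1 (0.00173), ICAM1 (0.00197), BIRC3 (0.00702), TNFAIP3 (0.0131) and NPM1 (0.0358). Without C2, BAD was at -0.038, CEBPB at -0.12, CRELD2 at -0.069, PSMB3 at -0.040, SRM at -0.10, GCLC at 0.073, NOP58 at 0.087, EZH2 at 0.057 and BCL2 at 0.079. Median, mean and direction of the test differed in sign for the p53, BCL2, plasma cell, stress response, proteasome and NF-kB lists, none of which was called.

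Markers of other cell types were at low levels or did not pass the filter on low counts. None of the T and NK cell or erythroid markers passed that filter, and the mitochondrially encoded genes were not analysed here. The myeloid markers CD68 and LYZ reached a mean of 3.02 and 2.40 CPM, with log2 differences of -0.35 (SE 0.171) and 0.23 (SE 0.212). The stromal marker ACTA2 reached 5.02 CPM (0.10, SE 0.131), and the 4 tested epithelial markers KRT8, KRT18, CDH1 and KRT5 at most 2.01 CPM. None of the 7 differed past the threshold, over all genes or adjusted over the list alone, and the myeloid and epithelial lists had camera adjusted p = 0.782 and 0.698.

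Transcripts as a set were much less precise than genes. The coefficient of variation between replicates, fitted as a shared value for each set, was 0.956 for transcripts and 0.051 for genes. It was 0.0652 for the 3934 transcripts with at least 100 reads on average and 80% of their gene's reads. The higher value therefore does not describe these transcripts. Of 43979 transcripts tested with edgeR, 1 passed, the IGFBP3 transcript NM_000598.4, which rose by 0.90 (SE 0.036, adjusted p = 0.0283); no transcript passed when any 1 library was left out. At an unadjusted p under 0.05 there were 1693, DESeq2 on the same counts called 746, and the authors' deposited table lists 1214 with a q-value under 0.05. The most abundant AURKA transcript, XM_017028035.1, was at -0.93 (adjusted p = 0.707), with a mean of 1033 expected counts in control and 549.5 in AURKA-guide libraries.

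The authors' deposited table of changed genes lists 229 genes, 110 higher and 119 lower with the AURKA guide. Of these, 226 passed the filter here, all 226 had the same sign in the edgeR fit and 202 were also called, while 65 genes called here are not in that table. Several of its largest changes rest on few reads. ABHD14A-ACY1, a readthrough gene with a log2 ratio of 21.3 in the authors' deposited table, had 138.6 expected counts in A1 and 0 in the other 5 libraries, at least 46-fold higher over the group against a floor of 3 counts but resting on 1 library. C4A, a complement gene with a near-identical neighbour, is listed at 6.49 in the authors' deposited table; it had 0 counts in the control libraries and 11.6, 15.4 and 24.1 in the AURKA-guide libraries, at least 16.9-fold higher against the same floor. For NT5C1B-RDH14, also a readthrough gene, and for XIRP1 and EGR1 the authors' deposited table gives 5.05, 1.84 and 1.95. Its largest falls are the unnamed gene 107986729 (-5.47, with 0 counts in the AURKA-guide libraries, at least 8.37-fold lower against the same floor), LOC110384692 (-2.65), OAS2 (-2.08), HES7 (-1.76) and LOC102724642 (-1.74; called here, and lost without C1 0.0872, A1 0.0521, A2 0.0597, A3 0.0744).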

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

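Groups of 3 libraries are too small for the test of single samples, and the comparisons below were chosen after the tables were seen. The transcript table also holds a comparison that no library of this series covers, NSD2 guide over control: 1394 transcripts have a q-value under 0.05 in the authors' deposited table. The NSD2 transcript NM_133335.3 has a log2 ratio of -10.3 there (q-value 4.04e-11). The same transcript had 0 expected counts in AURKA-guide replicate 1 as well, beside 212.4 and 192.3 in the other AURKA-guide libraries, and the most abundant NSD2 transcripts, NM_001042424.2 and XM_011513557.2, are at 0.09 and 0.04 in the NSD2 comparison of the authors' deposited table.

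The AURKA and NSD2 comparisons in the authors' deposited table share 337 transcripts with a q-value under 0.05, 335 of them in the same direction. Much of the AURKA list consists of minor transcripts: of its 1214, 914 had under 1 read in every library of 1 group, their median share of the gene's reads was 3.88%, and of their 1052 genes 87 changed at gene level. Among 3934 transcripts with at least 100 reads on average and 80% of their gene's reads, 39 were higher with the AURKA guide and 107 with the NSD2 guide, 14 with both, where independent lists would share 1.06. For lower transcripts the numbers were 29, 12 and 1 (VIM), against 0.0885, and TXNDC5 moved in opposite directions. The 14 are HLA-DRA, HLA-DRB1, HLA-DPB1, HLA-DOA, HLA-DMB, HLA-DQA2, HIST1H1C, HIST1H2BK, HIST2H2BE, IGFBP3, MTRNR2L8, CREG1, CBX1 and the unnamed gene 105369230. IGFBP3 is at 0.90 with the AURKA guide and 0.55 with the NSD2 guide in the authors' deposited table, HIST1H1C at 0.69 and 0.57, and HLA-DRA at 0.36 and 0.39.

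Both comparisons carry the same control name in the authors' deposited table. Comparisons against 1 set of controls share their chance values: 2 simulated unchanged groups against simulated controls had a correlation of log2 fold changes across transcripts with a median of 0.496 (100 draws), against 0.381 observed. In 10 draws they shared no called transcript. As no simulated comparison had more than 5 calls, this gives no reference for the 14 shared transcripts. The observed covariance was 0.00839, beside a simulated median of 0.00496 and a highest of 0.00636. Each transcript was drawn on its own, so deviations that real control libraries share across transcripts, such as trends with GC content, are not represented. If these are the same 3 control libraries, no split of them leaves 2 in each part, so part of the excess can come from the shared controls: control libraries low in a gene raise it in both comparisons.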

How the results depend on the processing

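AURKA fell past the threshold under every alternative except the minimum absolute log2 fold change of 1, which it does not reach. The count of changed genes ran from 98 to 2034 over the fits without 1 library (53 to 905 higher, 45 to 1129 lower): 98, 101 and 154 without AURKA-guide replicates 3, 2 and 1, 111 without control replicate 1, 234 without control replicate 2 and 2034 without control replicate 3. It was 866 (465 higher, 401 lower) with GC correction and 952 (513 higher, 439 lower) with GC and length correction, both chosen after seeing the data, and 36 (17 and 19) at an absolute log2 fold change of at least 1, a subset by construction. With a mean of at least 10 CPM it was 186, with 90 lower, over fewer genes. Other filters, scalings and tools gave 196 to 272, and the DESeq2 Wald test called 267, of which 214 were shared. Of 6 called lists, 3 were called with an estimated correlation. For transcripts, leaving out any 1 library gave 0 (0 to 0), and DESeq2 gave 746; the cause was not tested. Of 43 named genes called, 18 lost the call in at least 1 fit without a library and none changed sign. Over 80 named genes besides AURKA and all alternatives, 1038 of 1168 values kept direction and side of the threshold, 58 lost and 72 gained a call, and none reversed. Depth limits what can be said of genes at a few CPM.

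With the replicate number as a block, 385 genes and 0 transcripts were called, and the replication, histone, cholesterol and MTRNR2-like lists were not called with an estimated correlation (adjusted p = 0.258 for the first 3 and 0.0986 for the last). The labels do not say whether the numbers pair the samples. Same-numbered libraries correlated at 0.132, -0.138 and 0.331 in their deviations from the group means, and 3 of 6 libraries correlated best with their own number. With so few libraries these values cannot decide whether the samples are paired.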

Other observations

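The 7 gene lists added in this part and the GC corrections were chosen after seeing the data, as were the tests of the fold kept without control replicate 2 and of the mitotic genes called after GC correction. List p-values here were adjusted over these 7 lists alone. As the lists were chosen with the values in view, the p-values describe them and are not independent evidence. The list of histones with polyadenylated forms shares HIST1H2AC and HIST1H2BD with the replication-dependent histone list. C1 to C3 and A1 to A3 are control and AURKA-guide replicates 1 to 3. Genes of antigen presentation by MHC class II were higher in AURKA-guide libraries: of 14 tested, 10 rose and none fell (12 higher adjusted over the list alone, median 0.31, camera adjusted p = 6.1e-17, adjusted p = 0.0631 with an estimated correlation). HLA-DRA rose by 0.36 (SE 0.0432, adjusted p = 4.01e-04), HLA-DQA1 by 0.53 (SE 0.0594, adjusted p = 2.23e-04) and CIITA, the master regulator of class II, by 0.36 (SE 0.0693, adjusted p = 0.0113), while the invariant chain CD74 was at 0.13 (SE 0.0596, adjusted p = 0.312). Of the 10, 3 kept their calls without each library in turn (HLA-DRA, and the close copies HLA-DQA1 and HLA-DQA2, whose reads can be divided wrongly). The other 7 lost theirs: CIITA (A1 0.0599, A2 0.0513, A3 0.0811), HLA-DMB (A2 0.0564), HLA-DPA1 (C1 0.0681, A2 0.0564, A3 0.0608), HLA-DRB1 (C1 0.0916, A1 0.0547, A2 0.0676), HLA-DOA (C1 0.135, A2 0.104, A3 0.106), HLA-DPB1 (C1 0.167, A1 0.101, A2 0.181, A3 0.0988) and HLA-DMA (C1 0.166, A1 0.144, A2 0.121, A3 0.167). None of 12 class I genes changed (median -0.0016, camera adjusted p = 0.913; 0.0407 with GC and length correction, where adjusted p = 0.0973 with an estimated correlation), with B2M at 0.04 (SE 0.0542).

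Of 10 S100 and annexin genes, 3 fell, S100A10 by 0.44 (SE 0.0614), S100A11 by 0.39 (SE 0.0647) and ANXA2 by 0.22 (SE 0.0478), with 5 lower adjusted over the list alone (camera adjusted p = 1.55e-04, adjusted p = 0.0712 with an estimated correlation); calls were lost for S100A11 (A3 0.0589) and ANXA2 (C1 0.0993, A1 0.0937, A2 0.0861, A3 0.245). Of 13 Notch pathway genes HES7 and TLE2 fell, over all genes and over the list alone, while NOTCH2, RBPJ and HEY1 were at 0.09 (SE 0.054), 0.12 (SE 0.0654) and -0.20 (SE 0.0934), none past the threshold (camera adjusted p = 0.00787, adjusted p = 0.0752 with an estimated correlation). The Notch list was made after HES7 and TLE2 were seen to fall. It was not called among genes with a mean of at least 10 CPM, which leaves out HES7 and TLE2 (0.950), with no filter on low counts (0.264) or after GC correction (0.0516), with a range over all alternatives from 0.0014 to 0.950. Of 22 lysosomal genes the glucosidase GAA and the mannosidase MAN2B1 fell by 0.65 (SE 0.0882) and 0.33 (SE 0.0607), and the protease CTSB rose by 0.22 (SE 0.0477), with 3 lower and 1 higher over the list alone (camera adjusted p = 0.00733, adjusted p = 0.180 with an estimated correlation); calls were lost for MAN2B1 (C1 0.0748, A2 0.0969, A3 0.078) and CTSB (C1 0.152, A1 0.101, A2 0.158, A3 0.15). Of 14 linker and core histone genes with polyadenylated forms 6 rose, such as HIST1H2AC by 0.56 (SE 0.082) and HIST1H2BD by 0.43 (SE 0.0772; lost without A2 0.0751, A3 0.0564), while the replacement histones H3F3A and H2AFZ were at -0.00098 (SE 0.0551) and 0.04 (SE 0.0481) (7 higher and 1 lower over the list alone, camera adjusted p = 1.04e-07, adjusted p = 0.0631 with an estimated correlation). Of 8 MTRNR2-like genes, near-copies of mitochondrial rRNA whose reads are uncertain, 4 rose, among them MTRNR2L9 by 0.48 (SE 0.0659) and MTRNR2L8 by 0.30 (SE 0.0477), with 6 higher over the list alone; calls were lost for MTRNR2L1 (C1 0.1, A1 0.0547, A2 0.124, A3 0.139) and MTRNR2L2 (A1 0.0538, A3 0.0515) (median 0.24, camera adjusted p = 2.03e-08, adjusted p = 0.0267 with an estimated correlation). The latter call of the MTRNR2-like list was lost in 5 of the 6 fits without a library (C1 0.0705, C3 0.135, A1 0.0933, A2 0.0786, A3 0.0673) and after GC correction (0.119, median 0.17).

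The first pattern weighed is the count of changed genes. The libraries differed in their trend with GC content, from a slope of 0.117 (log2 per 10 points of GC percent) in control replicate 2 to -0.0632 in control replicate 3, with 0.00802, -0.0445 and -0.0639 in A1, A2 and A3, so that control replicate 3 lay nearer to A2 and A3 than to the other controls in this. A candidate explanation for the 2034 calls without that library, with a median GC of 40.6% for higher and 60.1% for lower genes, is that GC trend: with GC correction in both fits the count without it was 1.07 times that in all 6 (927 and 866), against 7.62 times without correction. GC bias does not account for the 267 genes as a whole, since 99.2% of those with a GC value kept call and sign after correction. Their median absolute log2 fold change went from 0.398 to 0.36. Keeping a call is a lenient criterion, as the correction also added 609 calls. GC bias may account for part of single fold changes: the median GC was 58.6% for lower, 47.2% for higher and 48.5% for all tested genes. Without control replicate 2, the library farthest out, a median of 96.3% of the log2 fold change of the called genes remained. In all 267 the groups did not overlap, which favours a high share. The value therefore cannot decide whether that library set the fold changes. Of the calls 77.9% remained, too few to exclude that it decides some of them. Of the 10 splits of 6 libraries into 3 and 3, 1, the real split, gave as many genes (267, highest other 1) and as many transcripts (1, highest other 0), and 10 splits are too few for a share under 0.05; an effect of the AURKA guide stays open for these genes as a hypothesis.

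The second pattern is the rise of class II genes. GC bias is argued against, as the list median was 0.324 after GC correction and 0.307 before. Reads moved between HLA-D copies would leave their sum unchanged, but the summed HLA-D reads of 13 genes rose with a log2 ratio of 0.308, from 1771 ± 74.9 to 2193 ± 42.8 CPM (SD, n = 3 each), with every AURKA-guide value above every control value. A biological response to the AURKA guide may remain as a hypothesis, and low class II levels in this set of control cells, which by its name also serves the NSD2 comparison, stay open and were not tested.

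The third pattern is the rise of the G2/M genes, which have low GC content. GC bias may account for part of it: the median fell to 0.134 from 0.19 with GC correction, between the values set beforehand for and against that cause. As the whole cause, the GC trend as modelled here is argued against by the shift left after the correction. The quartiles of the list were then 0.0938 and 0.197, and camera with an estimated correlation called the list (adjusted p = 0.0106). The criterion for this was chosen after seeing the data and also asked for at least 6 called members. That part could hardly fail, since 6 were called before the correction and calls over all genes rose from 267 to 866. The 15 of 30 members then called, all higher, therefore carry no weight. Control replicate 2 alone is argued against by a median of 0.158 without it. An effect of the AURKA guide on these genes stays open as a hypothesis.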
